A study of Mus musculus with 28 samples.

How the data were processed

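Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in 28 libraries from mouse embryonic fibroblasts (MEFs). Per the labels, the fibroblasts came from embryos, lacked Tet2 and carried doxycycline-inducible reprogramming factors (OKSM) with the rtTA activator. Libraries were made with a modified Fast-ATAC protocol and sequenced on an Illumina NextSeq 500, per the labels' protocols. The 7 groups of 4 libraries each were untreated MEFs (day 0), and day 5 and day 10 reprogramming cells that had received an empty pMXs retrovirus, wild-type Tet2 (Tet2-WT) or a Tet2 mutant that the series calls stalling (Tet2-E). The reprogramming cells were sorted on SSEA1-RFP, and the labels name no sorting for the MEFs. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates were separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

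The authors deposited 1 list of MACS2 peaks per library, so peaks were called per library and not on pooled samples. Bowtie2, SAMtools, bedtools, MACS2 and the mouse build mm9 are named in the submitters' processing notes; versions, settings, read filters and any shift of the cut sites are not given in the sources used here. In the deposited lists, the fold of each peak is the ratio of its summit pileup plus 1 to the local background of its own library plus 1. It is used as the authors' peak caller wrote it, and it is lower than the plain ratio of pileup to background. The lists also hold the authors' -log10 p and -log10 q of each summit. The lowest deposited -log10 q was just above 2 in every library, which is a q of 0.01. The deposited score of each peak was the authors' -log10 q times 10, and each list gives the position of the summit. Fold, score and p belong to a peak within its own list, so they were used to describe, rank or filter peaks within that list and never to compare levels between libraries.

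Peaks on 20 chromosomes (1 to 19 and X) were kept, and peaks on unplaced sequences were counted separately. Overlapping peaks of all libraries (1 bp or more) were merged into regions, and regions called in at least 2 of the 28 libraries were kept. A library called a region when at least 1 of its peaks overlapped it. Coordinates are those of mm9, counted from 1. The calling status of each region was compared between groups by 2-sided exact tests of the number of libraries that called it, for regions called in at least 2 of the compared libraries. MEFs were compared with the 12 libraries of each later day by Fisher's exact test. Day 5 was compared with day 10 by an exact conditional test stratified by vector, and the vectors were compared in pairs by the same test stratified by day. P-values were adjusted over regions by the Benjamini-Hochberg method, with a threshold of 0.05. A region is called gained where its share of calling libraries rose past that threshold, and lost where it fell. Values per library were compared by 2-sided exact permutation tests of 4 against 4 libraries, whose smallest p is 0.0286, adjusted over 15, 9 or 3 contrasts. The overlap of 2 peak sets was measured as the Jaccard index, the base pairs shared over the base pairs covered by either.

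Read totals were not used here. The relative depth was instead inferred from the lists, since each fold and p came from the same pileup and background under the caller's Poisson model. These gave whole-number summit pileups for 100% of peaks in each of the 28 libraries, with a tolerance of 0.0002 in -log10 p. The commonest background value of a library, the expected pileup at a position of the genome, was taken as its relative depth. It is an inference from the peak lists, not a read count. It also depends on the length given to each fragment in the pileup, a setting that is not given.

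The region tests were tested on simulated data with 109954 regions, of which 200, 2000 or 20000 had a nearly complete change. For MEFs against day 5, they recovered 0%, 56.8% and 94.7% of them. For day 5 against day 10 they recovered 84.0% of 200 and 99.0% of 2000. For Tet2-WT against the empty vector, with the simulated change present at both days, they recovered 0%, 55.4% and 96.4%. That comparison would thus miss 200 regions changed at both days and find most of 2000. A change at a single day was not simulated. No pair of libraries held identical lists.

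Named regions were chosen by a fixed rule. For each comparison of days, the 10 gained and 10 lost regions came first by p, then by difference in share, then by the median of the authors' fold over the libraries that called them. Where no region passed, the 5 regions in each direction called in 4 of 4 libraries of one vector and 0 of 4 of the other at day 10 with the highest median fold were taken. The 2 regions with the smallest p for Tet2-WT against the empty vector were named in addition, after their values were seen. The alternatives tried were a stricter peak threshold (-log10 q of at least 5), an equal number of peaks per library (the best 27809), a larger overlap, fixed windows of 500 bp, regions in at least 1 or at least 4 libraries, unplaced sequences kept, each replicate number left out, and the replicate number as a block. Gene annotation and sequence of mm9 were not used here, so regions carry no gene names, and promoter shares, motifs, gene lists and a check of the Tet2 transgene were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.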

Results

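Chromatin accessibility was profiled during reprogramming of Tet2-deficient fibroblasts to pluripotency, with wild-type Tet2, the stalling mutant Tet2-E or an empty vector returned to the cells. TET enzymes oxidise 5-methylcytosine in steps, and a mutant that stalls separates the first oxidation product from the later ones. The design therefore asks how chromatin opens and closes from MEFs to day 5 and day 10, and whether wild-type and stalling Tet2 change that course. Each of the 7 groups held 4 libraries.

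MEF libraries held 55688 ± 12810 peaks (SD, n = 4), the highest mean of the 7 groups. At day 5 the libraries held 49353 ± 7935 peaks with the empty vector, 52332 ± 4527 with Tet2-WT and 48360 ± 4899 with Tet2-E (SD, n = 4 each). At day 10 they held 36706 ± 4060, 39741 ± 8376 and 36942 ± 8155 peaks in the same order. Single libraries ranged from 27918 to 72332 peaks. None of the 15 contrasts between groups passed correction in exact permutation tests (lowest adjusted p = 0.171). Over the 3 vectors together, a comparison added after the data were seen, peaks fell from 50015 at day 5 to 37796 at day 10 (exact permutation within vectors, p = 0.000146). The relative depth also differed between days. The genome background pileup was 0.503 ± 0.113 in MEFs (SD, n = 4), 0.865 ± 0.0731 at day 5 and 0.522 ± 0.115 at day 10 (SD, n = 12 each). In each vector all 4 day 5 libraries lay above all 4 day 10 libraries (exact permutation p = 0.0286, adjusted p = 0.0714). Across the 12 day 10 libraries, peaks per library followed that background (Pearson r = 0.83, permutation p = 0.00092, adjusted 0.00276; Spearman rho = 0.86, permutation p = 0.00062, adjusted 0.00124; 6 relations tested), and r was 0.77 without the 2 libraries farthest from the median. Across the 12 day 5 libraries it did not (Pearson r = 0.012, permutation p = 0.972, adjusted 0.972; Spearman rho = 0.021, permutation p = 0.955, adjusted 0.955), and r was -0.19 without the 2 farthest.

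**Figure D1:**
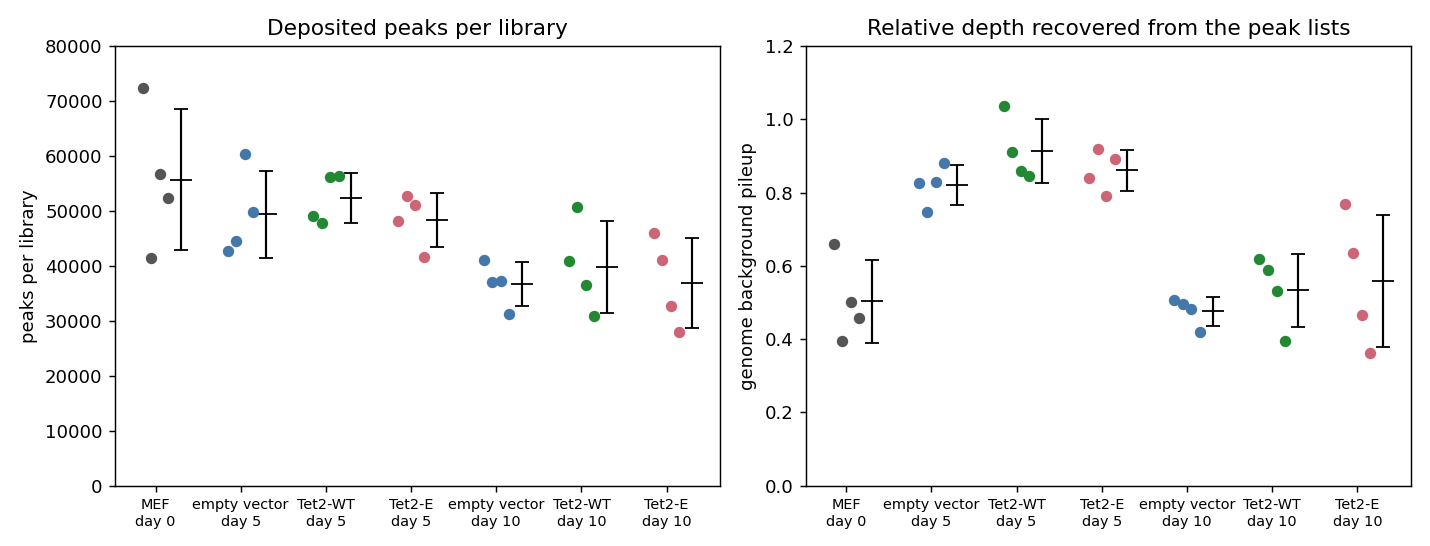
Peaks per library (left) and the genome background pileup recovered from the peak lists (right) for the 7 groups; each point is 1 library, and bars show the mean and SD of 4 libraries. Peaks range from 27918 to 72332, and the background ranges from 0.746 to 1.04 at day 5 and from 0.361 to 0.768 at day 10, with all day 5 libraries of a vector above all its day 10 libraries.

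Peak sets separated MEFs from all reprogramming cells, and day 5 from day 10, while no difference between vectors passed the test. The mean Jaccard index was 0.459 between MEF libraries, 0.467 between day 5 libraries and 0.407 between day 10 libraries. It was 0.231 between MEFs and day 5, 0.201 between MEFs and day 10, and 0.386 between day 5 and day 10. The 6 contrasts of MEFs with a reprogramming group and the 3 contrasts of day 5 with day 10 each passed (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0476). Within-group similarity exceeded between-group similarity by 0.223 to 0.236 for MEFs and by 0.0418 to 0.0518 for the days. The index depends on the length that a list covers, on average 10.6 Mb at day 5 and 7.29 Mb at day 10. The smaller difference between the days was therefore not separated from depth. The 6 contrasts of vectors did not pass, with differences from -0.00722 to 0.000512 (exact permutation, lowest adjusted p = 0.429). Merging the peaks gave 109954 regions, of which 7740 were called in all 28 libraries. These constant regions had a median fold of 9.21, by the authors' peak values.

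**Figure D2:**
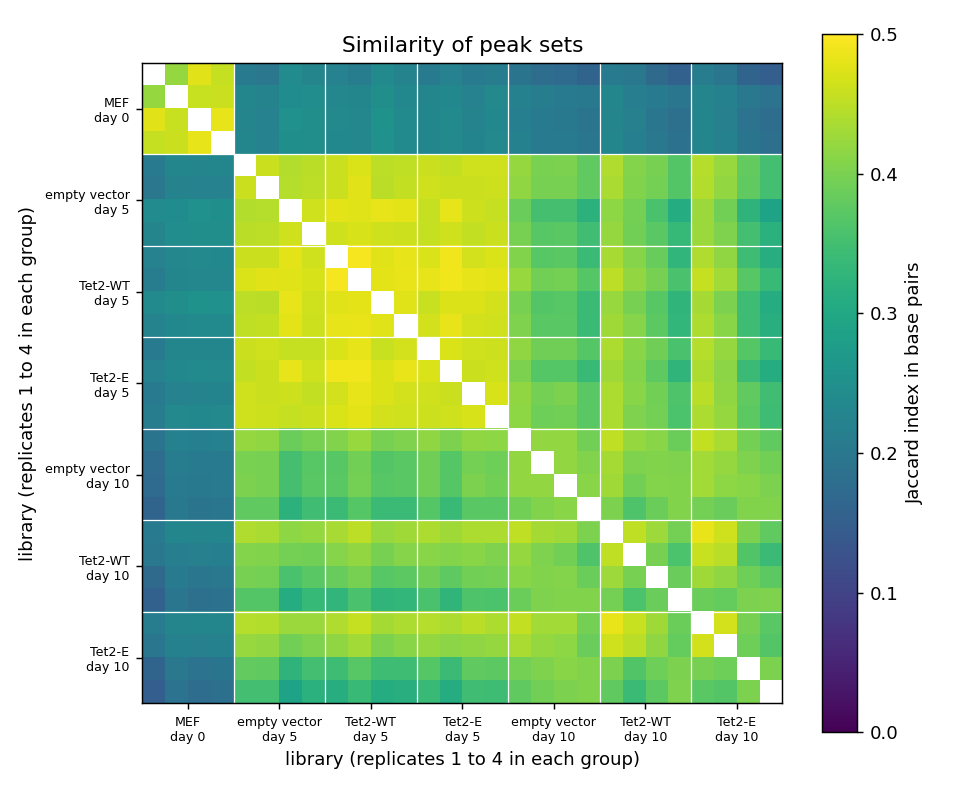
Jaccard index in base pairs between the peak sets of each pair of the 28 libraries, ordered by group and replicate; the diagonal is left blank. Pairs of a MEF with a day 5 library average 0.231, and pairs of day 5 libraries average 0.467 over all vectors.

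The first comparison asks which regions were called less or more often at day 5 than in MEFs. The MEFs were untreated, with no sorting named, and their background pileup averaged 0.503 against 0.865 at day 5. Sorting, vector and depth therefore cannot be told apart from the passage to day 5. Between MEFs and day 5, 9721 regions were gained and 15980 were lost of 99090 tested, so that 62.2% of the changed regions were lost. Many of these changes were complete in the peak lists. A set of 5467 regions was called in 0 of 4 MEF and 12 of 12 day 5 libraries, and 6662 regions went from 4 of 4 to 0 of 12. With peaks covering at least 50% of a region, 3864 were gained and 15689 lost, a lost share of 80.2%. That rule is harder to meet with narrow peaks, and the median peak width averaged 194 bp in MEFs and 165 bp at day 5. Among regions in at least 4 libraries, 9721 were gained and 10601 lost, a lost share of 52.2%. Of the changed regions, that filter left out only lost ones. Counts of complete changes with 4 libraries on each side were added after the data were seen. Of the regions in 4 of 4 against 0 of 4, 48.2% to 56.1% were lost in the 3 vectors, and 53.0% to 55.3% with an equal number of peaks per library. These counts keep only complete changes, so they do not isolate the effect of comparing 4 with 12 libraries. Among the complete gains, the highest fold lay on chromosome 6 at 101620434 to 101621101 (median fold 14.1). It was followed by regions on chromosome 9 at 79678492 to 79679354 (13.8), chromosome 10 at 129856670 to 129857631 (13.6), chromosome 6 at 93579837 to 93580282 (13.6) and chromosome 10 at 49137033 to 49137518 (13.4). The next 5 lay on chromosome 15 at 81407446 to 81407849, chromosome 5 at 16474487 to 16475188, chromosome 4 at 95351266 to 95351949, chromosome 14 at 112918076 to 112918233 and chromosome 15 at 91694412 to 91695056. All 10 were called in 0 of 4 MEF libraries and in 4 of 4 libraries of each vector at both day 5 and day 10 (Fisher's exact p = 0.000549, adjusted p = 0.00449 for day 5).

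Among the complete losses the highest fold belonged to chromosome 6 at 122565815 to 122566128 (median fold 21.1), chromosome 8 at 63343696 to 63344070 (20.9) and chromosome 6 at 96003486 to 96003805 (20.6). Next came chromosome 6 at 146134096 to 146134473 (19.9), chromosome 13 at 32976698 to 32976991 (19.7) and chromosome X at 65616574 to 65616748 (19.5). Regions on chromosome 10 at 124693002 to 124693321, chromosome 17 at 73621076 to 73621599, chromosome 17 at 42380833 to 42381171 and chromosome 18 at 13084356 to 13084617 completed the 10. Each was called in 4 of 4 MEF libraries and 0 of 12 day 5 libraries (Fisher's exact p = 0.000549, adjusted p = 0.00449). At day 10 the first 9 were still called in 0 of 12, and the last in 1. Without replicate 1, 2, 3 or 4 of every group, 6594, 6020, 6034 and 6272 regions were gained and 7153, 10197, 9050 and 8849 were lost, where 3 MEF against 9 day 5 libraries allow no Fisher's exact p under 0.00455.

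By day 10 the balance lay further on the side of lost regions. Of 89226 regions tested against MEFs, 5053 were gained and 20123 were lost, a lost share of 79.9%. With an equal number of peaks per library the lost share was 68.8% (4634 gained, 10225 lost). Among regions in at least 4 libraries it was 74.5% (5053 gained, 14744 lost). With peaks covering at least 50% of a region it was 95.9% (788 gained, 18642 lost). That last rule is harder to meet with narrow peaks, and the median peak width averaged 194 bp in MEFs and 148 bp at day 10. The 95.9% is therefore not separated from peak width. Complete changes numbered 2343 regions from 0 of 4 to 12 of 12 libraries and 10762 from 4 of 4 to 0 of 12. In counts of complete changes with 4 libraries on each side, added after the data were seen, 71.5% to 75.9% were lost in the 3 vectors, and 61.0% to 63.6% with an equal number of peaks. The 10 leading complete gains were those of day 5, and the 6 leading complete losses were also the same (Fisher's exact p = 0.000549, adjusted p = 0.00374). The other leading complete losses had still been called in some day 5 libraries. Chromosome 12 at 102721785 to 102722109 (median fold 19.4) was called in 1 of 12 at day 5, chromosome 9 at 73753653 to 73754191 (18.9) in 2, chromosome 11 at 11839521 to 11840005 (18.6) in 2 and chromosome 1 at 96046535 to 96046979 (18.4) in 3. Each was in 0 of 12 at day 10. Without replicate 1, 2, 3 or 4 of every group, 2594, 2528, 2824 and 3362 regions were gained and 11744, 15428, 12207 and 12592 were lost.

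**Figure D3:**
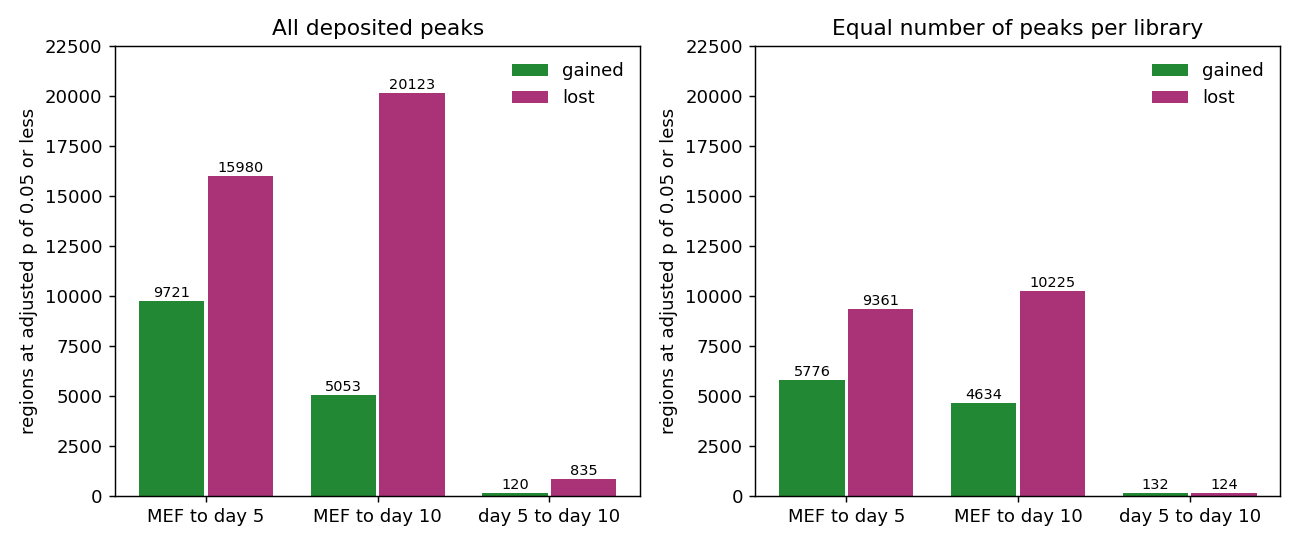
Number of regions gained and lost at an adjusted p of 0.05 or less in the 3 comparisons of days, with all deposited peaks (left) and with an equal number of peaks per library (right). Lost regions exceed gained ones from MEF to either day in both panels, but from day 5 to day 10 only with all peaks (835 against 120; 124 against 132 with equal numbers).

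Most regions gained or lost by day 10 were already past the threshold at day 5. Among 81807 regions tested against MEFs at both days, 4341 were gained at both, which is 46.7% of the 9289 gained by day 5 and 87.4% of the 4964 gained by day 10. A further 15604 were lost at both, which is 97.6% of the 15980 lost by day 5 and 77.5% of those lost by day 10. Independent lists of these lengths would share 564 gained and 3931 lost regions. Both comparisons use the same MEF libraries, which can make the lists agree. Random assignments of the 28 libraries called no region, so the shared lists were compared at unadjusted Fisher's exact p under 0.05. There 5510 regions were gained and 17680 lost at both days, against medians of 15.5 and 69 and highest values of 415 and 946 in 100 random assignments. These assignments remove every difference between groups, so their lists are short whatever the shared MEF libraries do. They cannot show how far the shared MEF libraries made the lists agree. With 2 different MEF libraries for each day and the same threshold, 3085 regions were gained and 8883 lost at both days, where independent lists would share at most 485 and 2063. At that threshold none or all of the MEF libraries used had to call a region. Every choice of libraries therefore gave the same counts, and the effect of shared MEF libraries was not isolated.

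The number of regions that changed between day 5 and day 10 depended on the regions and libraries tested. Of 83195 tested, 120 were gained and 835 were lost (exact conditional test stratified by vector), with 10165 at unadjusted p under 0.05. There were 165 gained and 1367 lost among regions in at least 4 libraries, and 45 and 1457 with peaks covering at least 50% of a region. The latter rule is harder to meet with the narrower day 10 peaks. In tests chosen after the data were seen there were 255 and 2370 among only regions able to reach p 0.001, and 109 and 211 without the day 10 libraries numbered 4. With replicates 1 and 2 against 3 and 4 as further strata, chosen after the data were seen, 0 passed (exact test, smallest p = 4.29e-05 against 5.83e-06 without these strata, smallest adjusted p = 0.054; 9738 at unadjusted p under 0.05). Of the 120 late gains, 109 were called in 0 MEF libraries and 93 were also gained from MEF to day 10. Of the 835 late losses, 600 were called in 0 MEF libraries and 536 were also called gained from MEF to day 5. Another 138 of the lost regions were called in all 4 MEF libraries. Among late gains in 0 of 12 day 5 and 12 of 12 day 10 libraries, the highest folds lay on chromosome 4 at 136720802 to 136721350 (median fold 7.92), chromosome 8 at 86281010 to 86281453 (7.55), chromosome 13 at 91008823 to 91009160 (7.40) and chromosome 13 at 38236888 to 38237352 (7.20). Late gains on chromosome 9 at 108198948 to 108199247, chromosome 19 at 4719327 to 4719755, chromosome 15 at 5966629 to 5966847 and chromosome 19 at 56989577 to 56989944 followed. All 8 were called in 0 MEF, 0 of 12 day 5 and 12 of 12 day 10 libraries (exact p = 5.83e-06, adjusted p = 0.0135). The next on chromosome 2, at 128066210 to 128066618, had the same p and was also called in 2 MEF libraries. A neighbouring region at 128091101 to 128091575 was called in 1 of 12 day 5 and 12 of 12 day 10 libraries (median fold 10.4, exact p = 2.92e-05, adjusted p = 0.0135).

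Late losses from 12 of 12 to 0 of 12 libraries were led by fold by chromosome 7 at 94335282 to 94335651 (median fold 8.74), chromosome 5 at 51596530 to 51596877 (8.68), chromosome 2 at 68174801 to 68175118 (7.76) and chromosome 2 at 118050086 to 118050457 (7.67). Chromosome 16 at 65406079 to 65406524, chromosome 14 at 92318576 to 92319437, chromosome 8 at 63211819 to 63212224, chromosome 3 at 137145569 to 137146262, chromosome 16 at 26721462 to 26721858 and chromosome 5 at 29580433 to 29580855 were the others. All 10 were called in 12 of 12 day 5 and 0 of 12 day 10 libraries (exact p = 5.83e-06, adjusted p = 0.0135), and 1 of them, chromosome 2 at 68174801, in 1 MEF library. With an equal number of peaks per library 132 regions were gained and 124 lost, a lost share of 48.4% against 87.4% with all peaks, while at unadjusted p under 0.05 2785 regions were called less and 1697 more often at day 10. No region passed without replicate 1, 2, 3 or 4 of every group (0 gained and 0 lost; exact test, adjusted p from 0.100 to 0.172; 7002, 6205, 5183 and 5209 regions at unadjusted p under 0.05), and without Tet2-WT day 10 replicate 2 alone 147 were gained and 1290 lost.

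Chromatin open in MEFs was measured directly on the 27904 regions called in all 4 MEF libraries. At day 5, 55.1% ± 5.67 of them were called with the empty vector, 56.0% ± 3.49 with Tet2-WT and 52.7% ± 2.32 with Tet2-E (SD, n = 4 each). At day 10 the shares were 45.0% ± 2.32, 45.6% ± 3.88 and 44.7% ± 4.54. In each vector all 4 day 10 libraries lay below all 4 day 5 libraries (exact permutation p = 0.0286, adjusted p = 0.0857). Over the 3 vectors together, a comparison added after the data were seen, the share fell from 54.6% to 45.1% (exact permutation within vectors, p = 5.83e-06, the smallest possible). With an equal number of peaks per library it fell from 53.4% to 49.8% (exact permutation p = 1.17e-05). There the regions called in all 4 MEF libraries were defined anew on the shortened lists, so they are not the same 27904 regions. At day 10 the share followed the background pileup over the 12 libraries (Pearson r = 0.87, permutation p = 0.00015, adjusted 0.0009; Spearman rho = 0.90, permutation p = 0.00012, adjusted 0.00036; r = 0.82 without the 2 farthest). At day 5 no such relation passed (Pearson r = 0.0951, permutation p = 0.772, adjusted 0.927; Spearman rho = 0.252, permutation p = 0.43, adjusted 0.645; r = 0.0471 without the 2 farthest).

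Chromatin outside MEF peaks was measured as a share of each list. Peaks that overlapped no MEF peak made up 43.5% ± 1.48, 44.8% ± 1.35 and 44.1% ± 2.19 of each list at day 5 for the empty vector, Tet2-WT and Tet2-E (SD, n = 4 each). At day 10 they made up 40.3% ± 2.48, 43.3% ± 5.09 and 40.6% ± 4.91. None of 9 contrasts passed (exact permutation, lowest adjusted p = 0.771). Over the 3 vectors together, added after the data were seen, the share fell from 44.2% to 41.4% (exact permutation within vectors, p = 0.0444). With an equal number of peaks per library, MEF libraries included, it went instead from 47.3% to 48.2% (exact permutation p = 0.088). It followed the background pileup at day 10 (Pearson r = 0.777, permutation p = 0.00294, adjusted 0.00588; Spearman rho = 0.909, permutation p = 0.00011, adjusted 0.00036; r = 0.805 without the 2 farthest). At day 5 no such relation passed (Pearson r = 0.183, permutation p = 0.575, adjusted 0.863; Spearman rho = 0.14, permutation p = 0.667, adjusted 0.801; r = -0.136 without the 2 farthest). Regions of the day 10 state were largely present at day 5. Of 4756 regions in 0 MEF and at least 10 of 12 day 10 libraries, 90.0% ± 1.82, 92.4% ± 1.99 and 90.7% ± 3.14 were called at day 5 with the empty vector, Tet2-WT and Tet2-E (SD, n = 4 each). No contrast of vectors passed for this share (exact permutation, lowest adjusted p = 0.343).

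**Figure D4:**
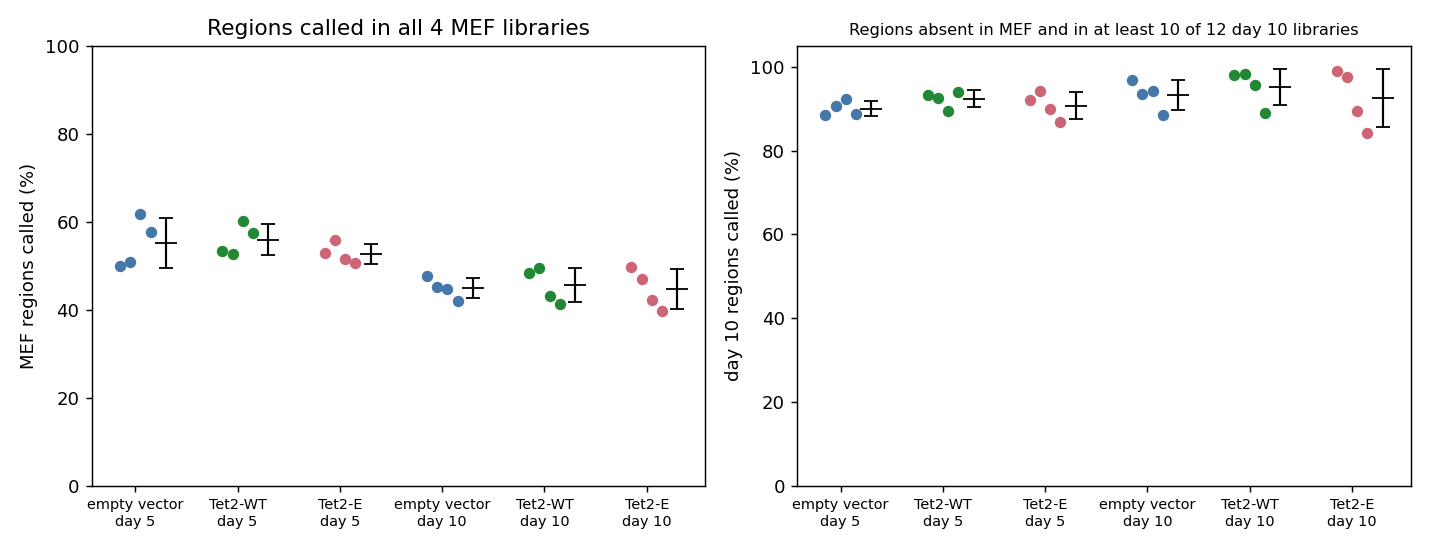
Percentage of the 27904 regions called in all 4 MEF libraries (left), and of the 4756 regions called in 0 MEF and at least 10 of 12 day 10 libraries (right), that each library called; points are libraries, bars the mean and SD of 4. The left shares lie at 50.1% to 61.8% at day 5 and 39.8% to 49.7% at day 10, and the right ones at 86.8% to 94.2% at day 5; the day 10 libraries on the right defined their own set.

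Wild-type Tet2 against the empty vector tests what restoring Tet2 did in Tet2-deficient cells. No region passed of 74168 tested over both days (exact conditional test stratified by day, smallest adjusted p = 1). At unadjusted p under 0.05 there were 525 regions, 407 called more often with Tet2-WT and 118 less often; with an equal number of peaks per library these were 195 and 133. Without Tet2-WT day 10 replicate 2 there were 880, and again none passed (exact test, smallest adjusted p = 1). A pair of regions was called in 8 of 8 Tet2-WT and 0 of 8 empty vector libraries, on chromosome 10 at 111432917 to 111433229 (median fold 6.64) and chromosome 2 at 16777005 to 16777371 (6.24) (exact p = 0.000408, adjusted p = 1). Both were called in 0 of 4 MEF libraries. With Tet2-E, the region on chromosome 10 was called in 2 of 4 day 5 and 0 of 4 day 10 libraries, and the region on chromosome 2 in 4 of 4 and 0 of 4. Within day 10, 130 regions were in 4 of 4 Tet2-WT and 0 of 4 empty vector libraries, and 35 the other way. Those with the highest fold called with Tet2-WT were on chromosome 16 at 48675652 to 48676024, chromosome 1 at 52856164 to 52856547, chromosome 8 at 42872601 to 42873153, chromosome 4 at 76577406 to 76577964 and chromosome 1 at 90017049 to 90017404. The first 4 had been called in 4 of 4 libraries of each vector at day 5. Those called with the empty vector were on chromosome 1 at 90422699 to 90423181, chromosome 2 at 135493289 to 135493734, chromosome 1 at 16536540 to 16537112, chromosome 3 at 96144794 to 96145212 and chromosome 16 at 77444315 to 77444642. Of the 35 splits of these 8 day 10 libraries, 11 gave as many such regions, and at day 5 (143 and 53 regions) 9 of 35 did. With an equal number of peaks per library 149 such regions were found at day 10, 44 of them with the empty vector, and 2 of 35 splits gave as many. At day 5 the counts were 65 and 44, and 15 splits gave as many. About 606 regions at the smallest possible p would have been needed for any to pass among all tested regions. Among only the 577 regions able to reach p 0.001, a set chosen after the data were seen, 0 passed (exact conditional test, smallest adjusted p = 0.118; 11 at unadjusted p under 0.05).

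The stalling mutant against the empty vector gave fewer regions at unadjusted p under 0.05. No region passed of 71000 tested (exact conditional test, smallest adjusted p = 1), and 340 had an unadjusted p under 0.05, 173 called more often with Tet2-E and 167 less often. Within day 10, 49 regions were in 4 of 4 Tet2-E and 0 of 4 empty vector libraries and 50 the other way, and 33 of 35 splits gave as many. The leading 5 called with Tet2-E included the regions on chromosome 1 at 52856164 and chromosome 8 at 42872601 named for Tet2-WT, with chromosome 7 at 107137332 to 107137546, chromosome 3 at 4386723 to 4387091 and chromosome 12 at 87003786 to 87004113. These regions on chromosomes 1 and 8 were called in 4 of 4 Tet2-WT and 4 of 4 Tet2-E day 10 libraries and in 0 of 4 with the empty vector, while at day 5 all 12 libraries called them. The leading 5 with the empty vector were on chromosome 15 at 74798471 to 74798989, chromosome 5 at 58134668 to 58135431, chromosome 13 at 118516577 to 118517258, chromosome 16 at 26234259 to 26234528 and chromosome 15 at 7881562 to 7882028. At day 5 the counts were 61 and 54, and all 35 splits gave as many.

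The stalling mutant against wild-type Tet2 is the comparison that separates stalled from complete oxidation. No region passed of 73329 tested (exact conditional test, smallest adjusted p = 1). Of 404 regions with an unadjusted p under 0.05, 93 were called more often with Tet2-E and 311 less often; with an equal number of peaks per library these were 120 and 155. Without Tet2-WT day 10 replicate 2 there were 730, and none passed (exact test, smallest adjusted p = 1). Within day 10, 33 regions were in 4 of 4 Tet2-E and 0 of 4 Tet2-WT libraries and 68 the other way, and 26 of 35 splits gave as many. At day 5 these counts were 34 and 114, with 28 of 35 splits. With an equal number of peaks per library they were 47 and 55 at day 10 and 54 and 54 at day 5. Regions called with Tet2-E at day 10 were led by chromosome 1 at 90422699 to 90423181, chromosome 7 at 109566016 to 109566353, chromosome 19 at 33441228 to 33441381, chromosome 3 at 52046489 to 52046770 and chromosome 1 at 160883502 to 160884009. Those called with Tet2-WT were led by chromosome 3 at 127632896 to 127633167, chromosome 5 at 107508894 to 107509412, chromosome 3 at 36122318 to 36122577, chromosome 7 at 148549309 to 148549616 and chromosome 5 at 30339331 to 30340045.

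The regions that had changed by day 10 were followed at day 5 in each vector. Of the 20123 lost regions, 11% ± 6.40 were still called at day 5 with the empty vector, 10.9% ± 4.48 with Tet2-WT and 7.44% ± 2.52 with Tet2-E (SD, n = 4 each). Of the 5053 gained regions, 90.4% ± 1.79, 92.7% ± 1.93 and 91.1% ± 3.05 were called at day 5 in the same order. The 6 contrasts of vectors on these sets, which were chosen after the data were seen, did not pass (exact permutation, lowest adjusted p = 0.6). No change from day 5 to day 10 in a difference between vectors passed for peaks per library, MEF regions called or peaks outside MEF regions (permutation of vectors within days, 4900 assignments, lowest adjusted p = 0.993). The differences per region of Tet2-WT and of Tet2-E from the empty vector correlated across 83195 regions (r = 0.514), which are not independent replicates. Unchanged groups with the same controls gave 0.499 ± 0.0149 (SD, 100 draws), and with different empty vector libraries for each vector r was 0.00159 to 0.024. The covariance was 0.0161 against 0.0156 in those draws, a difference of 0.000524.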

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

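The bounds on the lost share with equal numbers of peaks, the counts of 4 MEF against 4 later libraries, the comparison of each day's calls in 4 of 4 against 0 of 4 libraries with other splits, and the reassignment of all 3 vectors for regions in 8 of 8 against 0 of 8 libraries, were tests chosen after the results were seen. Of 53 groups and measures examined for a library that stands apart by Dixon's test, 3 had one, and chance sets apart about 1 in 20 groups. The peaks of Tet2-WT day 5 replicate 2 covered 10.2 Mb, against 11.5 to 11.6 Mb in the other 3 libraries of its group. Unplaced sequence of the Y chromosome lay outside the 20 chromosomes compared. It held 6 peaks in empty vector day 5 replicate 3 against 7 in each of the other 3, and 19 in Tet2-WT day 10 replicate 2 against 6 or 7. Peaks on that sequence averaged 7.96 ± 3.13 in the 24 reprogramming libraries (SD, range 4 to 19) and 1.25 ± 1.26 in the 4 MEF libraries (SD, range 0 to 3; permutation over all 20475 assignments, p = 0.000244). Each of the 6 reprogramming groups lay above the MEFs without passing correction (exact permutation p = 0.0286, adjusted p = 0.0714).

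Chance splits were excluded for the 3 comparisons of days. In each, only the real split of the 100 drawn (1 of 100) called any region, with 25701 regions from MEF to day 5, 25176 from MEF to day 10 and 955 from day 5 to day 10, and 0 as the highest of the other splits. Chance could not be excluded for the vectors by the number of regions at unadjusted p under 0.05. For Tet2-WT against the empty vector 11 of 100 splits gave as many (525; highest other 830), for Tet2-E against the empty vector 85 (340; highest other 837) and for Tet2-E against Tet2-WT 53 (404; highest other 860). Within day 5, as many regions in 4 of 4 against 0 of 4 came from 9 of 35 splits for Tet2-WT and the empty vector (196; highest other 362), 35 for Tet2-E and the empty vector (115; 276) and 28 for Tet2-E and Tet2-WT (148; 241). Within day 10 the numbers were 11 of 35 (165; 319), 33 (99; 390) and 26 (101; 612) in the same order. In each day 10 comparison, and for Tet2-WT and the empty vector at day 5, the highest split parted replicates 1 and 2 from replicates 3 and 4 of both vectors. That points to a structure of the samples other than the vector, for which the labels give no batch. Depth may enter it at day 10, where background pileup was higher in replicates 1 and 2 than in 3 and 4 of every vector (0.506 and 0.495 against 0.482 and 0.42 with the empty vector, 0.619 and 0.588 against 0.532 and 0.395 with Tet2-WT, 0.768 and 0.636 against 0.466 and 0.361 with Tet2-E).

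More regions were lost than gained from day 5 to day 10 (87.4% of those called). Greater depth of the day 5 libraries is a candidate explanation that stays open. With equal numbers of peaks 48.4% were lost. Lists of equal length push gains and losses towards balance, so this share cannot decide it. The extent of any depth effect is also not settled. With equal numbers 2785 regions were called less and 1697 more often at day 10 at unadjusted p under 0.05. Weak peaks at the end of the longer day 5 lists were not decided, because 54.3% of the day 5 peaks in the 835 lost regions lay in the weaker part of their list, split at the middle rank, between the bounds set for that test. For regions called in all MEF libraries, defined anew on the shortened lists, the share called fell from 53.4% to 49.8% with equal numbers of peaks (exact permutation within vectors, p = 1.17e-05). Equal numbers set the length of the lists and not depth itself. A closing of chromatin between the days was therefore not fully separated from depth.

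More regions were also lost than gained from MEF to day 10 (79.9%). With equal numbers of peaks 68.8% were lost. Lists of equal length push gains and losses towards balance, so this share cannot separate depth from closing. The background pileup was similar, at 0.503 ± 0.113 in MEFs (SD, n = 4) and 0.522 ± 0.115 at day 10 (SD, n = 12). It gave no sign that the day 10 libraries were shallower than the MEF libraries, but it is not a read count. A lower sensitivity of the day 10 lists for all regions is argued against as the whole cause. Of the strongest 6976 of the 27904 MEF regions, 26.4% were called in 0 of 12 day 10 libraries. The comparison of 4 MEF with 12 later libraries stays open together with depth. Counts of complete changes in 4 against 4 gave 71.5% to 75.9% with all peaks, but 61.0% to 63.6% with equal numbers. The lowest lay within the spread over vectors of the 60% set as the bound. These counts keep only complete changes, so they do not isolate the number of libraries. The sorting of the reprogramming cells, with 0 sorted MEF libraries, cannot be told apart from the passage to day 10, because the design has no sorted MEFs. A closing of more fibroblast chromatin than was opened was not tested apart from these.

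A pair of regions, on chromosome 10 at 111432917 to 111433229 and chromosome 2 at 16777005 to 16777371, was called in all 8 Tet2-WT libraries and in 0 of 8 empty vector libraries. The pair was picked as the highest count over 3 pairs of vectors and 2 directions. Of 100 assignments of the 3 vectors within days, 10 had a highest count of 2 or more (real 2; highest other 3), so chance could not be excluded. Within this pair of vectors alone, 1 of 100 splits, the real one, gave 2 (highest other 1). Neither region passed adjustment over 74168 regions (exact test, adjusted p = 1), and an effect of Tet2-WT on them was not tested otherwise.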

How the results depend on the processing

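The groups, tests, region rule and most alternatives were fixed before the data were examined. Chosen after the data were seen were the tests with replicates 1 and 2 against 3 and 4 as strata, the day 10 libraries numbered 4 left out, Tet2-WT day 10 replicate 2 left out, only regions able to reach p 0.001, both Tet2 vectors together, 4 MEF against 4 libraries of each vector, and days compared over all vectors. A stricter peak threshold, windows of 500 bp and unplaced sequences moved no count of gained or lost regions by over 1.5 times, and regions in at least 1 library could move none, since tested regions were in at least 2. Equal numbers of peaks gave 5776 gained and 9361 lost from MEF to day 5, 10225 lost from MEF to day 10 and 124 lost from day 5 to day 10. With peaks covering at least 50% of a region, 3864 were gained by day 5, 788 by day 10, and 45 gained and 1457 lost from day 5 to day 10. That rule is harder to meet with narrow peaks, and peaks were widest in MEFs and narrowest at day 10. Regions in at least 4 libraries gave 10601 lost from MEF to day 5, since that filter left out lost regions called in fewer libraries. The lost shares became 52.2% from MEF to day 5 and 74.5% from MEF to day 10. From day 5 to day 10 that filter gave 1367 lost, since fewer regions were tested. Only regions able to reach p 0.001 gave 5756 gained and 7811 lost by day 5, 2507 and 11641 by day 10, and 255 and 2370 from day 5 to day 10. With replicates 1 and 2 against 3 and 4 as strata 0 were gained and 0 lost from day 5 to day 10 (exact test, smallest adjusted p = 0.054; 9738 regions at unadjusted p under 0.05), and without the day 10 libraries numbered 4, 211 were lost. Leaving out a replicate number, or Tet2-WT day 10 replicate 2, gave 6020 to 9721 gained and 7153 to 15980 lost by day 5, 2528 to 5154 and 11744 to 20523 by day 10, and 0 to 147 and 0 to 1290 from day 5 to day 10, where the smaller design limits the p. The regions in 4 of 4 against 0 of 4 within a day numbered 824 over the 6 comparisons of vectors. As 3 of 3 against 0 of 3 without a replicate number they were 4021 to 4150, by construction. With 3 against 3 libraries the splits are too few for any contrast of similarity to pass, so the 0 that passed says nothing about stability. The share of peaks outside MEF regions over all vectors, lower at day 10 by -2.76 points, was higher by 0.954 points with equal numbers of peaks (exact permutation p = 0.088). The comparisons of vectors gave 0 regions under every alternative run, including both Tet2 vectors against the empty vector (exact conditional test; 1046 at unadjusted p under 0.05), but without a replicate number no p was under 0.005 and with the block none was under 0.00781, so a 0 there says nothing about stability. Differences that did not pass changed sign in 26 of 294 cases. Other causes were not tested.

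Same-numbered libraries of different vectors hardly deviated together (r from -0.0139 to 0.0374 at day 5 and from 0.00680 to 0.0902 at day 10), so the numbers were not treated as pairs. At day 10, 17 of 24 comparisons of a library with another vector gave the highest r for its own number, and background was highest in replicate 1 and lowest in replicate 4 of each vector, a hint from the data and not the design. With the replicate number as a block, 9054 regions were lost from MEF to day 5, 12174 from MEF to day 10, and 0 were gained and 0 lost from day 5 to day 10 (exact test, smallest adjusted p = 0.244; 7133 at unadjusted p under 0.05). Whether depth, recovered only from the peak lists, limits what the day 10 libraries could show is not settled, since MEF libraries had a similar background (0.503 against 0.522) and more peaks (55688 against 37796). Promoter shares, genomic location, motifs, gene lists and a check of the Tet2 transgene were not run, because annotation and sequence of mm9 were not used here.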

Other observations

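All tests in this part were written down before their results were seen, except the comparisons of chromosomes and 1 Mb bins and the grading of MEF regions by strength, which were chosen after the main results. MEF regions with strong peaks were called at later days more often than those with weak peaks. Among the 27904 regions in all 4 MEF libraries, ordered by the rank of the authors' p in the MEF lists, 59.7% of the strongest 6976 were called in 12 of 12 day 5 libraries and 52.8% in 12 of 12 day 10 libraries. For the weakest 6976 these shares were 18.2% and 11.1%. Conversely, 8.74% of the strongest 6976 and 35.5% of the weakest were called in 0 of 12 at day 5, and 26.4% and 45.8% at day 10. Weak peaks lie nearer the calling threshold and can be missed in a list without any closing. These shares therefore do not show that strong regions stayed open more often. Regions are not independent replicates, and no test was made.

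The loss of regions from MEF to day 10 was uneven over chromosomes, while no chromosome passed for gains. On chromosome 7, 18.3% of tested regions were lost against 22.8% elsewhere (Fisher's exact test across regions, adjusted p = 4.19e-14 over 20 chromosomes). Chromosomes 11 and 17 lost 18.8% each, chromosome 4 lost 20.2% and chromosome 19 lost 20.4%. Higher shares that passed were lost on chromosomes 18 (26.3%), 13 (25.6%), 1 (24.8%), 3 (24.7%), 12 and 8 (24.5% each), 16 (24.3%), 15 (24.2%) and 10 (24.0%). The lowest adjusted p for gains was 0.0558, on chromosome X (4.14% against 5.70%). Of 2111 bins of 1 Mb, 28 passed for losses, and for gains the lowest adjusted p was 0.314 (1-sided Fisher's exact test). Those with losses included chromosome 8 from 45000001 to 46000000, where 18 of 27 regions were lost (1-sided Fisher's exact test, adjusted p = 0.0026), and chromosome 16 from 24000001 to 25000000, where 25 of 48 were (adjusted p = 0.00821). Regions within a bin or chromosome can change together, so these p-values are too small. The tested regions were also not matched for the number of MEF libraries that called them.

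A hypothesis was that regions that changed by day 10 lie closer to each other than tested regions do. Of the gained regions, 8.19% had another gained region within 10000 bp, against 6.56% on average and 7.94% at most in 100 draws of as many tested regions. Of the lost regions, 25.9% had another, against 23.2% on average and 24.4% at most. Both shares lay above all draws. The drawn regions were not matched for width or for the number of libraries that called them. Clustering of changed regions beyond that of accessible chromatin as a whole was therefore not separated from this selection.

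Another hypothesis was that a vector changes the same regions at both days, so that its differences at day 5 and day 10 correlate across regions. For Tet2-WT against the empty vector r was 0.0145 with all peaks and 0.0120 with equal numbers, and 5 and 6 of 100 splits within days gave as much (highest other 0.0227 and 0.0164). For Tet2-E against the empty vector r was 0.0117 and 0.00694, with 11 and 18 of 100 splits (highest other 0.0195 and 0.0289). For Tet2-E against Tet2-WT r was 0.00434 and -0.00131, with 37 and 53 of 100 splits (highest other 0.0292 and 0.0275). Chance could not be excluded for any of these 6 correlations.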
